A study of Drosophila melanogaster with 39 samples.

How the data were processed

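FAIRE-seq and ChIP-seq of Drosophila wings and wing discs were measured by the submitters in the groups named in the labels: wild-type, E93-mutant and precocious-E93 tissue for FAIRE-seq, and tagged endogenous E93, precocious HA-tagged E93 and a driver-only control for ChIP-seq. Some of these samples were re-used by the submitters from earlier series, per the labels, and 6 are repeat sequencing runs of a library that counts here with its biological replicate. FAIRE tissue came from females, and ChIP tissue from males and females, per the labels' protocols. Antibodies against GFP at 24hAPF and against HA at 3LW were used at 5 µg per ChIP, so the stages also differ in tag and antibody.

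The submitters' processing notes name Bowtie2 2.2.8, SAMtools 1.3.1, Picard 2.2.4, bedtools 2.25.0, deepTools 2.24.0, MACS2 with a date as its version, featureCounts and DESeq2, without their settings, and the genome build dm3. Peaks were called by the authors in each ChIP library on its own, as the deposited peak names show, so replicates could be compared by position. In the deposited peak lists, the ratio column holds the authors' fold enrichment at the summit over background. The deposited −log10 columns hold p and q values from the authors' peak caller, and the lowest −log10 q in the lists was between 1.31 and 1.32. The deposited score column is the −log10 q multiplied and cut to a whole number by the authors' peak caller, and it was not used apart from this check. Fold and −log10 q belong to each peak and were mainly used to describe, rank or filter peaks within a list. Folds were also correlated between replicates and compared between the lists of both stages, to estimate a shift of X folds. That shift was then used to correct folds and fold minima. Folds also served to weight sites of a class to the folds of another, and groups of sites were compared in fold within each library. The input file holds 9420857 aligned reads of 35 bp, with a deposited mapping quality score of at least 30 for every read, and the authors' file name states a quality filter of 5 and removal of duplicates and of Y, unmapped and heterochromatic sequence.

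The authors deposited the FAIRE time course as a fraction of each site's maximum over 6 stages, with 1 pooled value per site and stage, and the maximum was tested to equal 1 at all 12373 sites. The signal behind these fractions and its normalization are not given in the sources used here, nor are the thresholds and tests behind the authors' categories of binding, E93 dependence, E93 sensitivity and wild-type change. A direction under precocious E93 is missing in the authors' deposited table for 2876 sites, all of which it calls insensitive. Every numeric column of the tables could be matched to a group or to a site property. The starts of the 12373 sites match the start of a deposited peak after a shift of 1 bp, and coordinates are given 1-based. Overlap with the peak lists gave the same class as the authors' deposited table at all but 21 sites.

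Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. Overlap needed at least 1 bp, and its expectation came from 1000 circular shifts of a list along each chromosome. Sites found in both replicates of a stage are the merged overlaps of the pair of lists. Differences in mean fraction were tested by two-sided permutation with 100000 resamples, with intervals from 1000 bootstrap resamples of sites, and shares by two-sided Fisher's exact tests. Intervals of shares are exact Clopper-Pearson intervals at 95% and those of differences of shares are Newcombe intervals. They cover counting error over sites only. Adjusted p values are Benjamini-Hochberg values within each family of tests. Opening and closing were set at a change of 0.25 in the fraction. On simulated data the overlap step recovered 51.7% where 50% of the sites had been planted, over 5842 sites. A true difference of -0.05 in the mean 3LW fraction between orphan and entopic sites was called in 100% of 100 simulated sets of 5789 sites, and no difference in 3% of 100 sets. For a difference of 5 percentage points in the dependent share the calls were 96.5% of 200 sets.

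Tests and main settings were fixed before the data were examined. Alternatives tried were a reciprocal overlap of 50%, summits within 200 bp, peaks with −log10 q of at least 10, equal numbers of top peaks, each ChIP library left out, other class definitions, other thresholds and stages, medians, and subsets of sites. The comparison of dependent with independent sites and of wild-type with precocious changes, the simulations of the shared 3LW libraries, the restriction to sites with a direction given and the count of sites on X, were added after the data were seen. A family of 6 tests of the shares gaining and losing among all sites of each class was also run after the data were seen and then left out, and the shares are given with their intervals only. The labels do not say whether the replicate numbers mark separate animals pooled on separate days, so replicate spread may be partly technical.

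The gene table of the reference follows a newer assembly than dm3, and coordinates were not converted, so no site was assigned to a gene or to a promoter, exon or intron. The tests of gene lists and genomic annotation fixed beforehand were therefore not run. The sites of br, nub, Tnc and Eip93F, to be named whatever their values, were likewise not looked up. After the files were seen, the rule for named genes was changed to apply to sites: the 8 strongest sites per class by mean rank of fold enrichment over the libraries that bind the class, and the 8 sites with the largest rise and fall of the FAIRE fraction from 3LW to 24hAPF, of which the leading ones are described. The driver-only ChIP and the FAIRE values of single libraries were not analysed here. Read depths of the ChIP and FAIRE libraries are not given in the sources used here, which leaves the precision of single sites unknown.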

Results

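E93, the product of the ecdysone-induced gene Eip93F, is a transcription factor of pupal development in Drosophila melanogaster. The series asked where E93 binds and how chromatin accessibility changes when E93 is expressed early, in wing imaginal discs of third-instar wandering larvae (3LW). In these discs an HA-tagged E93 was driven in the wing, which is called precocious E93 here, and it was compared with a GFSTF-tagged allele of E93 in wings at 24 hours after puparium formation (24hAPF). The labels list 39 samples. FAIRE-seq, which recovers nucleosome-depleted DNA and so measures open chromatin, accounts for 32 of them: 23 wild-type samples from 18 biological replicates at 6 stages from 3LW to 44hAPF, 6 samples of E93 mutants and 3 samples of precocious E93 from 2 biological replicates. ChIP-seq accounts for 6 samples in 3 groups, with 2 biological replicates each, and a genomic DNA input from adult females is the remaining sample. At least 700 wings went into each ChIP at 24hAPF and at least 200 discs into each ChIP at 3LW, per the labels, and both preparations mixed males and females. The values come from 4 peak lists, the input reads and 2 of the authors' deposited tables, which cover 12373 sites. The driver-only ChIP libraries were not analysed here.

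Precocious E93 at 3LW gave longer peak lists than tagged endogenous E93 at 24hAPF. The lists held 17278 and 13912 peaks in precocious replicates 1 and 2, and 11047 and 6716 peaks in 24hAPF replicates 1 and 2. Median fold enrichment over background, as the peak caller gave it, was 2.78 and 3.21 at 3LW and 3.11 and 3.21 at 24hAPF. At 24hAPF nearly every peak of the shorter list recurred: 95.4% of replicate 2 peaks were overlapped by replicate 1, and 56.2% of replicate 1 peaks by replicate 2. At 3LW the shares were 83.9% of replicate 2 peaks and 71.1% of replicate 1 peaks. In a permutation test by circular shifts of the lists along the chromosomes, mean overlaps were 6.13% and 3.75% at 24hAPF and 10.3% and 8.51% at 3LW, and every observed share lay above all 1000 shifts (one-sided permutation p = 9.99e-04, the smallest that 1000 shifts can give). Across sites found in both replicates, fold enrichment correlated between replicates with Spearman's rho of 0.827 over 6052 sites at 24hAPF and 0.730 over 11384 sites at 3LW. These correlations are across sites, which are not independent replicates. The read depth of the ChIP libraries is not given in the sources used here, so list length cannot be set against depth.

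Most sites bound by endogenous E93 at 24hAPF were also bound by precocious E93 at 3LW, whereas a smaller share of the precocious sites was bound at 24hAPF. Of the 6052 sites found in both 24hAPF replicates, 4953 (81.8%) overlapped a reproducible precocious site, against 8.90% for shifted positions. Of the 11384 sites found in both precocious replicates, 4800 (42.2%) overlapped a 24hAPF site, against 4.78% for shifted positions. Both shares exceeded all 1000 shifts (one-sided circular-shift permutation test, p = 9.99e-04, the smallest possible). Shifted positions are not matched for accessibility. The test therefore cannot tell shared E93 binding from a common preference for open chromatin or from ChIP background. Between single libraries, 70.8% to 85.9% of 24hAPF peaks were overlapped by precocious peaks, and 32.3% to 52.3% of precocious peaks by 24hAPF peaks. The share of precocious sites bound at 24hAPF rose to 59.5% when 24hAPF replicate 2 was left out. With the same number of top peaks taken from every library, 60.2% of 24hAPF sites and 60.0% of precocious sites were shared, and lists of equal length give nearly equal shares by construction. With 2 libraries per stage, no permutation of libraries can reach p = 0.05, so no test between libraries was made.

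The authors' deposited table divides the 12373 sites into 4691 entopic, 6584 ectopic and 1098 orphan sites. From their overlap with the peak lists, entopic sites had peaks in both replicates of both stages, ectopic sites in both precocious replicates but not in both 24hAPF replicates, and orphan sites the reverse, apart from 21 sites with peaks in all 4 lists. In shares, 37.9% of sites were entopic (95% exact interval 37.1% to 38.8%), 53.2% ectopic (52.3% to 54.1%) and 8.87% orphan (8.38% to 9.39%). Entopic sites were the widest, with a median of 620 bp against 380 bp for ectopic and 322 bp for orphan sites. Site edges are edges of deposited peaks and entopic sites hold peaks of all 4 lists, so merging alone may widen them. A class does not mean absence of binding at the other stage: 2081 ectopic sites (31.6%) had a peak in at least 1 24hAPF library, of which 1957 had it in replicate 1 alone, and 508 orphan sites (46.3%) had a peak in at least 1 precocious library.

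Sites shared by both stages were more strongly enriched than sites of a single stage. Within each library's own list, the median fold enrichment of shared peaks over that of stage-specific peaks was 1.208 ± 0.0108 at 24hAPF (SD, n = 2) and 1.302 ± 0.0249 at 3LW (SD, n = 2). By mean rank of fold enrichment, the strongest entopic site lay on chromosome 3L at 5244380 to 5244972 (build dm3), with a fold of 12.9 and 11.4 in the 24hAPF replicates and 11.6 and 16.8 in the precocious replicates. Its wild-type FAIRE fraction was 0.202 at 3LW and 0.668 at 24hAPF, and the authors' deposited table calls it increasing both in wild type and with precocious E93. Second was a site on 2R at 12709114 to 12709883, with folds of 10.3 and 9.10 at 24hAPF and 8.69 and 11.8 at 3LW. The strongest ectopic site, on 2R at 9447439 to 9449780, had folds of 10.2 and 15.0 at 3LW and no 24hAPF peak; the second, on X at 3350260 to 3351008, had folds of 12.1 and 12.9 at 3LW and 2.77 in 24hAPF replicate 1 alone. The strongest orphan site, on 2R at 18292580 to 18292945, had folds of 12 and 9.79 at 24hAPF and no precocious peak, and its wild-type FAIRE fraction rose from 0.201 at 3LW to its maximum of 1 at 24hAPF. All 8 of the orphan sites ranked strongest are increasing in wild type in the authors' deposited table. Genomic input reads differed by class in the 1 input library. Their density over shifted positions was 0.999 at entopic sites (95% Poisson interval 0.995 to 1.00). It was higher at ectopic sites, at 1.04 (1.038 to 1.047), and lower at orphan sites, at 0.902 (0.892 to 0.913). The contrast depended on the window. Over 200 bp at summits the values were 0.990 at ectopic, 0.931 at entopic (0.9244 to 0.9384) and 0.913 at orphan sites (0.8989 to 0.9275). The intervals of entopic and orphan sites then overlapped.

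Ectopic sites lay on chromosome X more often than entopic sites. X held 1262 ectopic sites (19.2%, 95% exact interval 18.2% to 20.1%), 619 entopic sites (13.2%, 12.2% to 14.2%) and 113 orphan sites (10.3%, 8.56% to 12.2%). The difference between ectopic and entopic sites was 5.97 percentage points (4.61 to 7.32; two-sided Fisher's exact test, p = 2.93e-17). It was present in the peak lists themselves, where X held 17.1% of peaks in each precocious library and 12.1% and 12.7% of peaks in the 24hAPF libraries. This comparison was chosen after the data were seen, and sites are not independent replicates.

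In wild-type wings the classes followed different time courses of accessibility. Orphan sites were the least open at 3LW, with a median FAIRE value of 0.335 of each site's maximum (interquartile range 0.181 to 0.559), and rose to 0.686 at 24hAPF. Ectopic sites started at 0.705 (0.448 to 0.991), fell to 0.528 at 18hAPF and came back to 0.675 at 44hAPF. Entopic sites went the other way, from 0.627 at 3LW (0.385 to 0.867) up to 0.741 at 18hAPF and down to 0.596 at 44hAPF. Highest accessibility fell at 3LW for 24.4% of ectopic, 13.5% of entopic and 4.92% of orphan sites, and at 24hAPF for 9.11%, 12.2% and 20.3%.

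**Figure D1:**
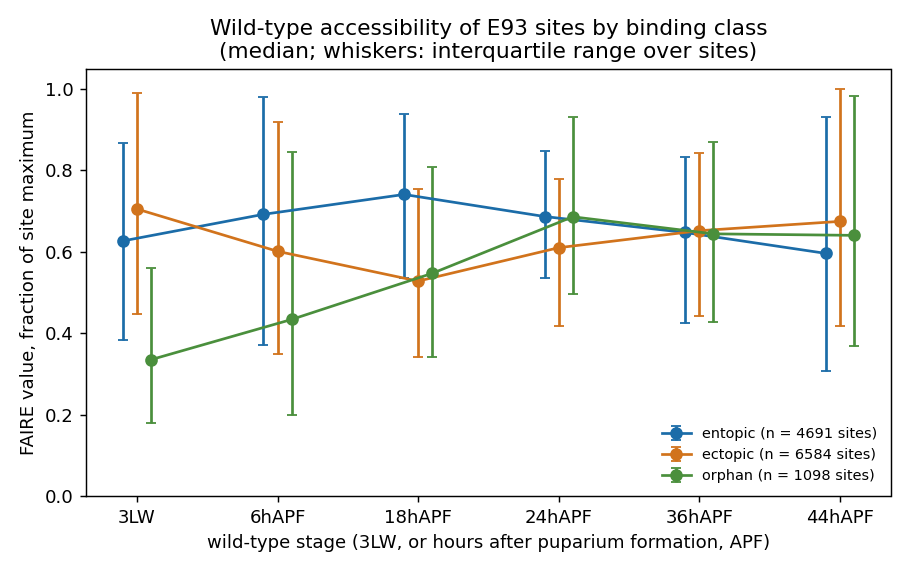
Median wild-type FAIRE value, as a fraction of each site's maximum over 6 stages, against stage for entopic, ectopic and orphan sites; whiskers are the interquartile range over sites. Orphan sites start at 0.335 at 3LW, below ectopic (0.705) and entopic (0.627) sites, and the medians of all classes lie between 0.61 and 0.69 at 24hAPF.

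At 3LW the mean fraction at orphan sites was 0.404 against 0.619 at entopic sites, a difference of -0.215 (95% bootstrap interval -0.234 to -0.197), and it was -0.275 from that of ectopic sites (-0.294 to -0.257). Ectopic sites had a mean of 0.679 and exceeded entopic sites by 0.0606 (0.0509 to 0.0712). At 24hAPF ectopic sites had the lowest mean, 0.604, against 0.683 at entopic sites (difference -0.0783, -0.0870 to -0.0704) and 0.679 at orphan sites. Each of these differences had an adjusted p of 1.20e-05 in two-sided permutation tests with 100000 resamples, from the smallest raw p they can give (Benjamini-Hochberg over 6 tests). Orphan and entopic sites differed by -0.0037 at 24hAPF (-0.0196 to 0.0118; adjusted p = 0.618), and this difference turned positive, at 0.0217 (adjusted p = 0.0129), when precocious replicate 2 was left out of the class definition. The table holds 1 pooled value per site and stage, so the spread is over sites, which are not independent replicates, and a fraction of a site's own maximum gives the shape of its time course and no absolute level.

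Most orphan sites opened between 3LW and 24hAPF, whereas ectopic sites closed more often than they opened. A rise of at least 0.25 in the fraction was seen at 611 of 1098 orphan sites (55.6%, 95% exact interval 52.7% to 58.6%), 1458 of 4691 entopic sites (31.1%, 29.8% to 32.4%) and 1219 of 6584 ectopic sites (18.5%, 17.6% to 19.5%). A fall of at least 0.25 was seen at 106 orphan (9.65%), 963 entopic (20.5%) and 2075 ectopic sites (31.5%). Every pair of classes differed in both shares (two-sided Fisher's exact test over sites, Benjamini-Hochberg over 6 tests, largest adjusted p = 9.44e-19). With 44hAPF in place of 24hAPF the order of ectopic and entopic sites in opening reversed: ectopic sites then opened more often, by 2.64 percentage points (adjusted p = 0.0025).

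The authors' deposited table gave the same order in its own wild-type categories. It calls 642 orphan sites increasing from 3LW to 24hAPF (58.5%), 1756 entopic sites (37.4%) and 1242 ectopic sites (18.9%), and it calls 2137 ectopic sites decreasing (32.5%), 1309 entopic sites (27.9%) and 122 orphan sites (11.1%). The site with the largest rise, on 3L at 11442235 to 11442653, was entopic and went from a fraction of 0.0250 at 3LW to 1 at 24hAPF and back to 0.176 at 44hAPF. The next, on 2L at 12116269 to 12116548, was ectopic and rose from 0.0276 to 1, and the third, an orphan site on 3L at 9202648 to 9202865, rose from 0.0312 to 1. The 8 largest rises ranged from 0.954 to 0.975. The largest fall was at an ectopic site on 3L at 12089565 to 12089822, from 1 at 3LW to 0.0351 at 24hAPF. The second and the third were neighbouring ectopic sites on 2L at 6086737 to 6088180 and 6085588 to 6086078, which fell to 0.0767 and 0.0794. The genes near these sites were not assigned here.

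Over all sites, loss of E93 affected orphan sites most often. The authors' deposited table calls 384 of 1098 orphan sites E93-dependent (34.97%, 95% exact interval 32.1% to 37.9%), against 1275 of 6584 ectopic sites (19.4%, 18.4% to 20.3%) and 799 of 4691 entopic sites (17.0%, 16.0% to 18.1%). Orphan sites exceeded entopic sites by 17.9 percentage points (15.0 to 21.0; two-sided Fisher's exact test over sites, adjusted p = 1.41e-35) and ectopic sites by 15.6 points (12.7 to 18.6; adjusted p = 6.09e-28), with Benjamini-Hochberg adjustment over 9 tests. The excess of ectopic over entopic sites was 2.33 points (0.886 to 3.76; adjusted p = 0.0029), but it fell to 0.8999 points (adjusted p = 0.254) when 24hAPF replicate 2, the library with the shortest list, was left out of the class definition. Dependence went with the wild-type time course: of the 3640 sites that the authors' deposited table calls increasing from 3LW to 24hAPF, 1289 were dependent (35.4%), 621 of 3568 decreasing sites (17.4%) and 548 of 5165 static sites (10.6%). The orphan lead did not hold within every wild-type category. Among increasing sites, 565 of 1242 ectopic sites (45.5%, 42.7% to 48.3%), 275 of 642 orphan sites (42.8%, 39.0% to 46.8%) and 449 of 1756 entopic sites (25.6%, 23.5% to 27.7%) were dependent. Among static sites the shares were 14.4% at orphan (10.8% to 18.6%), 13.2% at ectopic (12.01% to 14.39%) and 4.80% at entopic sites (3.81% to 5.95%). Among sites decreasing in wild type, 61 of 122 orphan sites (50%, 40.8% to 59.2%), 272 of 1309 entopic sites (20.8%, 18.6% to 23.1%) and 288 of 2137 ectopic sites (13.5%, 12.1% to 15.0%) were dependent. The stage and the threshold behind the dependent category are not given in the sources used here, so whether it uses the same wild-type libraries as the wild-type category is unknown.

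**Figure D2:**
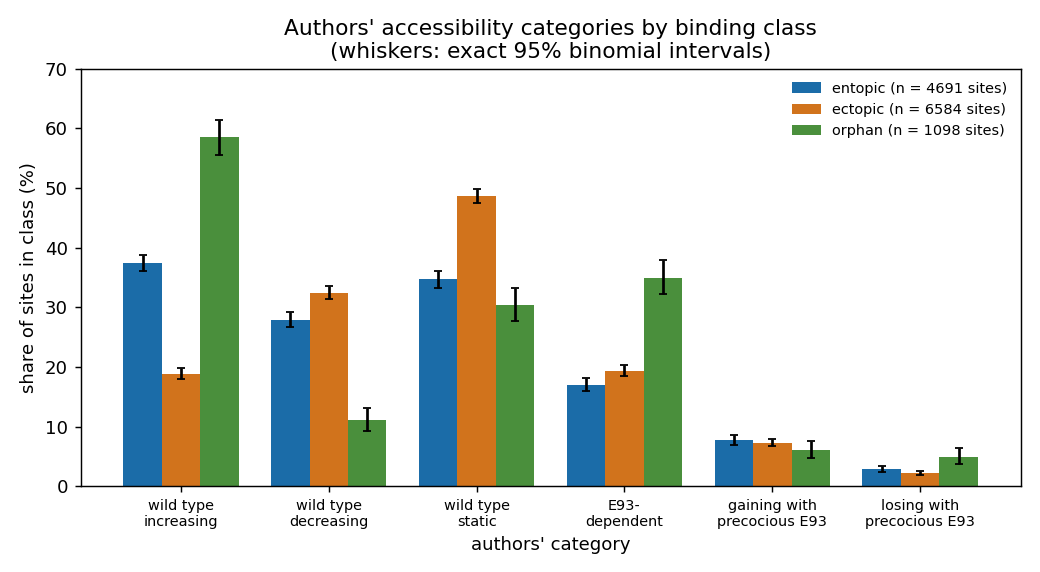
Share of entopic, ectopic and orphan sites, in percent, in each accessibility category of the authors' deposited table; whiskers are exact 95% binomial intervals. Orphan sites lead in the increasing (58.5%) and E93-dependent (34.97%) categories, and gains with precocious E93 lie between 6.01% and 7.76% when sites with no direction given, most frequent in the entopic class, count as not gaining.

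Precocious E93 changed accessibility at a minority of the E93 sites, and gains outnumbered losses. Of 12373 sites, the authors' deposited table calls 1248 sensitive to precocious E93 at 3LW (10.1%, 95% exact interval 9.56% to 10.6%), 912 with a gain and 336 with a loss. Sensitive sites made up 10.6% of entopic sites (499), 9.55% of ectopic sites (629) and 10.9% of orphan sites (120), and no pair of classes passed the test (two-sided Fisher's exact test, adjusted p from 0.0905 to 0.786). This depended on sites for which the table gives no direction and which count as insensitive: they make up 34.1% of entopic, 17.8% of ectopic and 9.56% of orphan sites. Among sites with a direction, 499 of 3093 entopic sites (16.1%), 629 of 5411 ectopic sites (11.6%) and 120 of 993 orphan sites (12.1%) were sensitive, and entopic sites then exceeded ectopic sites (ectopic minus entopic -4.51 points, adjusted p = 1.71e-08) and orphan sites (orphan minus entopic -4.05 points, adjusted p = 0.0028). This alternative was chosen after the data were seen. Losses were seen at 54 orphan sites (4.92%, 3.72% to 6.37%), 135 entopic sites (2.88%, 2.42% to 3.40%) and 147 ectopic sites (2.23%, 1.89% to 2.62%). Orphan sites differed from the other classes in direction. Gains made up 482 of 629 sensitive ectopic sites (76.6%, 73.1% to 79.9%), 364 of 499 entopic sites (72.9%, 68.8% to 76.8%) and 66 of 120 orphan sites (55%, 45.7% to 64.1%). The difference of ectopic minus entopic sites, 3.68 points (-1.39 to 8.82), did not pass (two-sided Fisher's exact test, adjusted p = 0.187). Orphan sites lay 17.9 points below entopic sites (difference -17.9, -27.6 to -8.43; adjusted p = 5.44e-04) and 21.6 points below ectopic sites (difference -21.6, -31.1 to -12.3; adjusted p = 8.85e-06). With 1 site per 50 kb window, chosen at random because neighbouring sites are not independent, these differences were -19.3 and -17.8 points and passed no test (adjusted p = 0.297).

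Sites that gained or lost accessibility with precocious E93 mostly changed the same way in wild-type development. Of the 912 gaining sites in the authors' deposited table, 666 (73.0%) increase from 3LW to 24hAPF in wild type, 224 are static and 22 decrease. Of the 336 losing sites, 312 (92.9%) decrease in wild type, 22 are static and 2 increase. Over the 1002 sensitive sites that also change in wild type, 978 (97.6%, 95% exact interval 96.5% to 98.5%) changed in the same direction. At entopic sites as the authors class them there was no exception, with 336 gains among 336 sensitive increasing sites and 0 gains among 126 sensitive decreasing sites, which allows a share of up to 2.89% (exact 95% interval). Exceptions appear with other class definitions, where the entopic difference between increasing and decreasing sites fell from 100 to as little as 97.6 points. At ectopic sites 279 of 280 sensitive increasing sites and 21 of 163 sensitive decreasing sites gained, and at orphan sites 51 of 52 and 1 of 45. Gains were also seen at static sites, at 182 of 3205 static ectopic sites (5.68%, 4.90% to 6.54%), 14 of 334 static orphan sites (4.19%, 2.31% to 6.93%) and 28 of 1626 static entopic sites (1.72%, 1.15% to 2.48%), with sites lacking a direction counted as not gaining and no test made between the classes. Both sets of calls are taken here to use the wild-type 3LW libraries, which the sources used here do not state. In a simulation with no effect at 2000000 sites, with 3, 3 and 2 libraries sharing the 3LW set and calls made at the observed rates of 58.3% changing and 10.1% sensitive, 92.6% of joint calls had the same direction. Joint calls were 1.22 times those of independent lists in the simulation and 1.38 times in the 1002 observed ones, and joint calls in the same direction were 2.252 times in the simulation and 2.68 times observed. The observed values lie above those without effect at these rates. With simulated calls made at p under 0.05 instead, 99.8% of joint calls had the same direction. Joint calls were then 3.09 times those of independent lists. The observed ratio could not reach that value, because 58.3% of sites were called changing. These values, from a far lower call rate, therefore cannot be set against the observed 97.6% and 1.38. The comparison thus depends on the simulated call rate, and real wild-type changes are absent from the simulation. The simulation assumes equal noise in all libraries and the 3LW libraries could not be split, so no p is given.

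**Figure D3:**
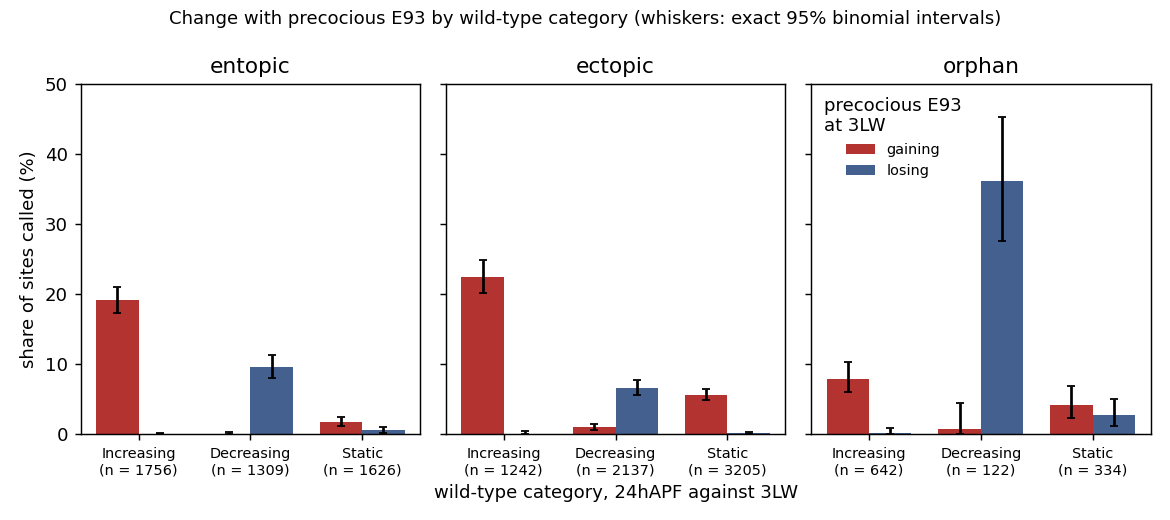
Share of sites, in percent, called gaining or losing accessibility with precocious E93 at 3LW in the authors' deposited table, by wild-type category and binding class; whiskers are exact 95% binomial intervals. Gains are most frequent at increasing sites (19.1% of entopic, 22.5% of ectopic and 7.94% of orphan sites) with a further 224 of 912 gains on static sites, and losses are most frequent at decreasing sites, where they reach 36.1% of the 122 orphan sites.

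Sites called E93-dependent were sensitive to precocious E93 more often than other sites. In the authors' deposited table, 580 of 2458 dependent sites were sensitive (23.6%, 95% exact interval 21.9% to 25.3%), against 668 of 9915 independent sites (6.74%, 6.25% to 7.25%), an odds ratio of 4.28 (two-sided Fisher's exact test over sites, adjusted p = 1.32e-112, 12 tests in the family). The odds ratio was 5.23 at entopic sites (226 of 799 against 273 of 3892), 4.12 at ectopic sites (284 of 1275 against 345 of 5309) and 2.96 at orphan sites (70 of 384 against 50 of 714), with adjusted p of 4.77e-56, 1.13e-54 and 4.70e-08. The stage of the dependent calls is not given, so these p values do not allow for wild-type libraries used in both calls. Dependence and sensitivity also both went with the wild-type category. The odds ratios were not adjusted for it, so they do not give the strength of the link within a category. Sensitive sites also made up 1002 of 7208 sites that change in wild type (13.9%) and 246 of 5165 static sites (4.76%), an odds ratio of 3.23 where the simulation with no effect gave 1.84 at the observed rates. By class the observed and simulated odds ratios were 7.62 and 1.77 at entopic, 2.45 and 1.94 at ectopic and 1.97 and 1.73 at orphan sites, and no p is given for the same reason as above. At entopic sites bound at both stages, 141 dependent sites gained accessibility and 81 lost it with precocious E93 in the direction of the wild-type change. The strongest of the gaining set lay on X at 11442980 to 11443460, with folds of 12.4 and 11.2 at 24hAPF and 7.08 and 8.93 at 3LW, and its wild-type fraction rose from 0.132 at 3LW to 1 at 24hAPF. In the losing set the strongest lay on 2R at 7068305 to 7068831, with folds of 9.55 and 9.59 at 24hAPF and 8.21 and 9.67 at 3LW, and its fraction fell from 1 to 0.346. The listing of these 2 sites was decided after the values were seen. For orphan sites the dependent odds ratio passed no test with 1 site per 50 kb window (difference 9.84 points, adjusted p = 0.0676).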

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

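The link between wild-type change and response to precocious E93 differed between binding classes. Sites changing in wild type had 7.62 times the odds of being sensitive compared with static sites at entopic sites, 2.45 times at ectopic sites and 1.97 times at orphan sites. The ratio of the odds ratios was 0.321 for ectopic over entopic sites (95% interval 0.219 to 0.472, adjusted p = 4.33e-08) and 0.258 for orphan over entopic sites (0.144 to 0.462, adjusted p = 1.62e-05), by a Wald test of the difference in log odds ratio, adjusted over 6 tests. For dependence on E93 the ratio of orphan over entopic sites was 0.566 (0.367 to 0.874, adjusted p = 0.0205). The shared 3LW libraries alone, simulated with no effect at each class's call rates, gave odds ratios of 1.77, 1.94 and 1.73 at entopic, ectopic and orphan sites, so the orphan value lies near the one without effect. Among sites with a direction given the 3 ratios were 0.293, 0.208 and 0.464, and the ratio of ectopic over entopic sites for dependence, 0.789 over all sites (adjusted p = 0.112), was 0.703 (0.534 to 0.926, adjusted p = 0.0183). These tests were chosen after the counts were seen, they treat sites as independent and allow for no shared library, and no explanation was tested for the differences.

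Technical explanations were weighed for a set of 3 patterns. The tests of near misses, of the shared 3LW libraries, of room to gain and of X dosage at 24hAPF were chosen only after the result was seen.

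Orphan sites had a lower wild-type 3LW FAIRE fraction than entopic sites. If orphan sites were only the weaker 24hAPF peaks (median fold 3.20 against 3.90), weighting entopic sites to the same folds should remove the difference, but it stayed at -0.214 (95% bootstrap interval -0.233 to -0.196). That value argues against weak 24hAPF peaks as the explanation. If near misses with a precocious peak in a single library made the difference, the 590 orphan sites with no precocious peak should resemble entopic sites. They differed by -0.258 (-0.281 to -0.235), so the difference did not rest on near misses. These sites were selected for having no precocious peak, so the value cannot decide on a threshold effect at 3LW. An untested candidate is that precocious E93 binds less often where chromatin is closed at 3LW. That hypothesis came from these same data and was not tested, and the pooled fractions give no replicate error.

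Ectopic sites lay on X more often than entopic sites. If weak 3LW peaks on X filled the ectopic class, its stronger part should come near the entopic X share. The part above the median 3LW rank exceeded that share by 8.31 points (6.62 to 10.0). This argues against weak 3LW peaks as the whole cause. The ranking used folds not corrected for X, and the comparison was with entopic sites of any 3LW rank. Dosage may contribute, because both preparations mixed males and females in unstated shares and X folds at entopic sites were 1.06 times higher at 3LW relative to 24hAPF; dividing the X folds at 3LW by that factor, under a common fold minimum, left 5.81 points (4.12 to 7.50). The outcome written beforehand as ruling dosage out was wrong, because that correction leaves the 24hAPF threshold, which divides ectopic from entopic sites, as it was; when 3LW-bound sites were regrouped by a 24hAPF fold minimum, failing sites exceeded passing sites on X by 4.72 points (3.29 to 6.11) without the factor and by 2.91 points (1.41 to 4.35) when autosomal sites needed folds higher by the factor. The corrected interval spans the bound of 2 points set for the test, so X dosage and a preference of precocious E93 for X cannot be told apart here. The anti-HA background in the driver-only libraries was not analysed.

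Precocious E93 changed accessibility in the direction of the wild-type change. Chance could give this if both sets of calls share the wild-type 3LW libraries, but the change from 6hAPF to 24hAPF uses none of them. That change was upward at 84.4% of gaining sites against 48.5% of insensitive sites, a difference of 35.9 points (33.2 to 38.3). At losing sites it was upward at 19.6%. Room to rise at sites low at 3LW could also favour gains, but within 20 bins of the 3LW fraction the difference was 20.4 points (17.8 to 22.8). Losing sites were not compared within such bins, so room to fall at sites high at 3LW was not tested. These values argue against the shared libraries as the whole cause, and at gaining sites against room to rise as the whole cause. A direct effect of E93 stays an untested hypothesis, since the size of the shared part is unknown. Orphan sites, which lack a reproducible precocious peak, were sensitive about as often as entopic sites (10.9% against 10.6%). Among sites with a direction given the shares were 12.1% and 16.1%.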

How the results depend on the processing

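Of 405 alternative values, 114 used planned settings and 291 used settings chosen after seeing the data. Planned were all settings of overlap, fold, input and numbers of sites per class. Other thresholds, stages and medians, and classes from both replicates' lists, were planned too. Those classes were also applied to comparisons that were themselves added after the data were seen. Other class definitions in the remaining comparisons, subsets of sites and the authors' wild-type categories came after. In 377 the side of the threshold, or the range, stayed, and all overlap shares stayed above their shifts. These include differences that changed sign but passed no test in either setting. Some values could not move. Associations over all sites stay the same when sites only move between classes. Leaving out a 24hAPF library cannot change the number of orphan sites, nor a precocious library that of ectopic sites. The cause was not tested unless given. With classes from any replicate's peak list, which need only 1 peak, there were 7280 entopic and 590 orphan sites; orphan minus entopic fraction at 24hAPF was 0.0236, ectopic minus entopic was -0.249 points in the dependent share, -1.25 points in the sensitive share and 6.54 points in gains among sensitive sites, and changing minus static in the sensitive share of orphan sites was 3.41 points. With strict classes (ectopic sites with no 24hAPF peak, orphan sites with no precocious peak) the dependent excess of ectopic sites was 1.69 points and the orphan changing minus static value 3.41 points. With 1 site per 50 kb, which leaves 1840 sites, the dependent excess of ectopic sites was 2.46 points, orphan gains were -19.3 and -17.8 points from entopic and ectopic sites, and the orphan sensitive share differed by 9.84 points with dependence and 5.71 points with wild-type change. Among sites with a direction given, the sensitive share was -4.51 points ectopic minus entopic and -4.05 points orphan minus entopic, since missing directions fall mostly on entopic sites. With 44hAPF as the later stage, ectopic minus entopic opening was 2.64 points. Leaving out each ChIP library gave ranges of 0.8999 to 1.918 points for ectopic minus entopic dependence (lost without 24hAPF replicate 2), -1.282 to -1.002 points for sensitivity (past the threshold without precocious replicate 1), -0.0145 to 0.0217 for orphan minus entopic fraction at 24hAPF and 4.75 to 5.71 points for orphan changing minus static (lost without precocious replicate 2). Without 24hAPF replicate 2, 59.5% of precocious sites were shared, in place of 42.2%, and 4608 sites were ectopic. The fold ratio of shared over stage-specific peaks was 1.24 at 24hAPF and 1.27 at 3LW with reciprocal overlap, and 1.62 and 2.40 in −log10 q. Input density over 200 bp at summits was 0.931 at entopic, 0.990 at ectopic and 0.913 at orphan sites. No paired analysis was possible because the overlaps come from no test across libraries and the labels do not tie equal replicate numbers to a shared batch. Not run: gene lists, genomic annotation and distal sites, which need an annotation of the same build, a fold-change threshold, and the replicate block.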

Other observations

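The authors' deposited table groups the sites into 8 clusters, and the clusters differed in gains, losses and dependence on E93. Cluster 3, highest at 18hAPF (median fraction 1) and 24hAPF (0.931), held 1278 sites, of which 61.3% were entopic, 21.3% were E93-dependent and 284 (22.2%) gained accessibility with precocious E93, while 0 lost it. Cluster 4, low at 3LW (0.280) and highest at 36hAPF (1), held 1086 sites, of which 61.2% were E93-dependent and 247 (22.7%) gained accessibility. Losses fell mainly in cluster 1, highest at 3LW (140 of 1221 sites, 11.5%), and cluster 2, highest at 6hAPF (126 of 1387 sites, 9.08%). In clusters 1 and 2 dependence was 18.2% and 25.5%, and gains were 0.819% and 2.96%. Gains were 7.63% in cluster 5, 2.97% in cluster 6, 7.49% in cluster 7 and 1.55% in cluster 8, and dependence 26.8%, 7.42%, 19.5% and 3.29%. Cluster 1 was 77.9% ectopic. No test was made between clusters, and how they were drawn is not given in the sources used here.

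The test of binding strength and that of neighbouring sites were written before their results were seen. Sites that gained accessibility had stronger precocious binding: median folds at ectopic sites were 3.45 and 3.92 in the precocious replicates at gaining sites against 2.91 and 3.08 at insensitive sites, and at entopic sites 4.68 and 5.28 against 3.84 and 4.19. Site width or the mix of classes could produce this, but within class and 10 bins of width the smaller difference of the pair of libraries was 0.25 on the log2 scale (95% bootstrap interval 0.22 to 0.27). A hypothesis consistent with this is that stronger occupancy goes with opening, although open chromatin may itself raise the fold, which was not tested.

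Sensitive sites within 10 kb of each other tended to change in the same direction, in 77.2% of 413 neighbouring pairs against a mean of 60.6% when directions were permuted freely. Neighbours also share their wild-type change: permuting directions within the wild-type category gave a mean of 74.1%, with a one-sided permutation p of 0.0040 over 10000 permutations. Most of the excess thus went with the wild-type category, and the remainder is small.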
